A study of Drosophila melanogaster with 3 samples.

How the data were processed

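Occupancy of V5-tagged DSXF and DSXM in S2 cells was measured by chromatin immunoprecipitation followed by sequencing. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min and chromatin was sheared to between 200 and 1000 bp. Libraries were made from 100 ng of immunoprecipitated DNA and from 300 ng of input DNA, per the labels. The DSXF sample pooled 3 biological replicates in 4 sequence runs (1 library was run again), the DSXM sample 3 replicates in 3 runs and the input 2 replicates in 2 runs. Per the series' design text, reads of all replicates of a sample were pooled before alignment and peaks were called on the pooled reads. The submitters' processing notes name Bowtie 0.12.7, Picard and the build dm3. The peak caller, its threshold, its control and its filters are not given in the sources used here.

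The deposited data used were 2 peak lists, 1 per isoform. Each has 3 columns without a header, namely sequence name, start and end, and no score, height, fold enrichment, p-value or summit. The positions are as the authors deposited them, with starts read as counted from 0 and printed here counted from 1. Sequence names such as XHet and U, tested on the files, are those of dm3. Each list was assigned to its isoform because the name under which it was deposited holds the title of that sample and no other. Pooling means that a region present in a single replicate cannot be told from one present in all, and that a deeper sample can yield more peaks. Read depth is unknown, so no depth-based precision can be given. Wilson and exact binomial intervals (95%) cover counting error over peaks only.

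Peaks were compared with scripts in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and the overlap counts were checked against bedtools 2.31.1, which gave identical numbers. The main definition of a partner was an overlap of at least 1 bp. Chance placement was described by 1000 circular shifts of the DSXM list within the extent of each sequence, which runs from the first to the last peak in either list; these extents, not chromosome lengths, were also used for densities. Differences of median width were tested with a two-sided permutation test over 100000 resamples, with a 95% interval from 1000 bootstrap draws of peaks, and the relation of log2 widths with a permutation test over as many. Shares per sequence were compared with Fisher's exact test and Benjamini-Hochberg adjustment. On simulated lists, 100% of planted copies moved by up to 100 bp were found and 19.1% of 6520 DSXF peaks met a list with no copies. The narrowest peak was 310 bp, so a copy moved that little must overlap its source. The 100% therefore checks the code only and says nothing about displaced edges or split peaks. On the widths of 600 DSXF peaks drawn at random and labelled at random, the median test called 5% of draws with no effect. It called 91% when the widths of 1 label were raised by 20%. These draws used fewer resamples and do not cover labels that depend on width, as overlap does.

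The comparisons, the definitions of a partner and the rule for named items were fixed before the data were examined. Tests planned on peak scores could not be run as written, because the files hold none; peak width took the place of the score, a choice made after seeing the files. Width is not a measure of binding strength. By the rule, items named by position were the 10 widest peaks and the 5 widest unpartnered peaks of each list and the 5 densest bins of 50 kb, of which those that matter are given. Assignment of peaks to genes, annotation classes, the search for the DSX binding motif and the tests of gene lists were planned for a dm3 sequence and annotation and were not run; the gene table used here is of Release 6, and positions were not converted between builds. No gene is therefore named. The planned check of peaks at sequence carried by the expression constructs, which the input cells lacked, was not run for the same reason, so some peaks in both lists may come from the constructs. Alternatives tried were other definitions of a partner (reciprocal overlap of 50%, centres within 200 bp, a gap of up to 500 bp), uniform placement in place of shifts, leaving out heterochromatic and unplaced sequences, and the widest 50% and 25% of each list. Replicates could not be left out in turn, since they were pooled.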

Results

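Doublesex (DSX) is the Drosophila transcription factor at the end of the somatic sex determination cascade, and sex-specific splicing of its transcript gives a female protein, DSXF, and a male protein, DSXM, that share the DNA-binding domain and differ at the C-terminus. The series mapped where each isoform occupied the genome of S2 cells, a cultured line of embryonic origin with macrophage-like properties. Cells carried a V5-tagged DSXF or DSXM construct and chromatin was immunoprecipitated with an antibody against the V5 tag. There were 3 samples: the DSXF immunoprecipitate and the DSXM immunoprecipitate, each from 3 biological replicates, and input DNA from untransfected cells, from 2 biological replicates. The replicates of a sample were pooled before alignment, so each isoform was represented by 1 peak list, without a replicate error. The lists give positions on the dm3 build and no height, fold enrichment or p-value. The read depth behind a peak is therefore unknown, and no test between the isoforms as conditions was possible.

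The first comparison asked how many peaks each list held and how broad they were. The DSXF sample had 4 sequence runs and the DSXM sample 3, and a deeper sample can yield more peaks. With depth unknown, differences in peak number or width do not show that DSXF occupied more or broader regions. The DSXF list held 6520 peaks covering 12.95 Mb and the DSXM list held 5370 peaks covering 10.8 Mb. Peak widths were alike in the lists: the median was 1544.5 bp for DSXF (quartiles 1146 and 2315 bp) and 1578.5 bp for DSXM (quartiles 1192 and 2360 bp). The narrowest peak was 310 bp in either list, and the widest was 25.6 kb for DSXF and 25.2 kb for DSXM. Peaks of 10 kb or wider numbered 12 for DSXF and 8 for DSXM. The median distance from one peak to the next was 5.86 kb for DSXF and 6.96 kb for DSXM.

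The second comparison asked which regions the isoforms shared. A peak was given a partner when a peak of the other list overlapped it by at least 1 bp. Of the DSXF peaks, 4483 of 6520 (68.8%, 95% Wilson interval 67.6 to 69.9%) had a DSXM partner. Of the DSXM peaks, 4578 of 5370 (85.3%, 84.3 to 86.2%) had a DSXF partner. The numbers with a partner are nearly equal, and the shares differ because the DSXF list is longer. Merging both lists gave 7232 regions, of which 4403 (60.9%) held peaks of both isoforms, 2037 held a DSXF peak alone and 792 a DSXM peak alone. The base pairs that lay inside peaks of both lists came to 9.17 Mb, which is 63.1% of the 14.5 Mb covered by either. This counts the overlapping parts only and not the full span of the merged regions.

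Overlap was far above that of shifted positions. When the DSXM list was moved by a random circular shift along each chromosome sequence, 16.6% of DSXF peaks and 20.0% of shifted DSXM peaks found a partner on average over 1000 shifts. The observed shares were 4.14 and 4.25 times these means, and 0 of 1000 shifts reached either of them. The size of these ratios depends on the definition of a partner: they were 3.56 and 3.61 with a gap of up to 500 bp allowed, 14.02 for both isoforms with a reciprocal overlap of 50% and 28.7 for both with centres within 200 bp. Wilson intervals and shifts describe counting and placement in these 2 lists and not the spread between cultures. The series holds 1 input sample for both isoforms, and part of the excess may come from this shared reference if it was used to call both lists. Both immunoprecipitates also came from the same cell line and used the same antibody. Neither shifts nor uniform placement keep peaks at like local features of the genome, such as gene density. The excess over them therefore does not show by itself that the shared peaks are shared DSX binding. An anti-V5 immunoprecipitate from untransfected cells was not analysed here.

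Partnered peaks coincided closely. There were 4180 pairs in which 1 DSXF peak met 1 DSXM peak and no other. Their centres lay a median of 54.2 bp apart, and 80.1% (95% Wilson interval 78.8 to 81.3%) were within 200 bp. The start positions differed by a median of 62 bp, as did the end positions, and no peak had the same start and end in both lists (0 peaks). Widths were related across these pairs, with Pearson's r = 0.888 on log2 width and Spearman's rho = 0.860, each with a permutation p of 1e-05, the smallest that 100000 resamples can give. In pairs formed by shifted positions the mean rho was -0.06 and the highest 0.29. Of 4166 pairs of unequal width, the DSXF peak was the wider in 2743 (65.8%, 64.4 to 67.3%), by a median of 63 bp over all pairs. Regions were also split differently: 167 DSXF peaks spanned 2 or more DSXM peaks, and 80 DSXM peaks spanned 2 or more DSXF peaks. Peaks are not independent replicates, so these p-values describe the lists only.

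Peaks seen with 1 isoform were narrower than shared ones. The median width of DSXF peaks was 1856 bp with a partner and 1142 bp without, a difference of 714 bp (95% bootstrap interval 669 to 757 bp across peaks; two-sided permutation p = 1e-05, the smallest possible). For DSXM the medians were 1678 bp and 1228 bp, a difference of 450 bp (407 to 494 bp; permutation p = 1e-05). The share of DSXF peaks with a partner was 32.3% (29.8 to 34.9%) in the narrowest of 5 equally large width classes and 96.9% (95.9 to 97.7%) in the widest. For DSXM the corresponding shares were 71.9% (69.1 to 74.5%) and 98.6% (97.7 to 99.2%). In shifted positions the shares were 13.4% and 22.99% for the same DSXF classes and 16.2% and 27.3% for the DSXM classes. Wider peaks thus met a partner more often by placement alone. The permutation tests with an overlap of at least 1 bp make no allowance for this, and median differences were not computed in shifts. When a partner was instead defined by centres within 200 bp, the difference was 286 bp for DSXF (permutation p = 1e-05), and for DSXM it was 24 bp and did not pass the test (permutation p = 0.41). Under that rule 1979 DSXM peaks were unpartnered, against 792 without any overlap, so most of the 1979 did overlap a DSXF peak. Their upper quartile of width was 2391.5 bp, against 1531 bp for the 792. For DSXM the rule thus does not set peaks seen with 1 isoform against shared ones.

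**Figure D1:**
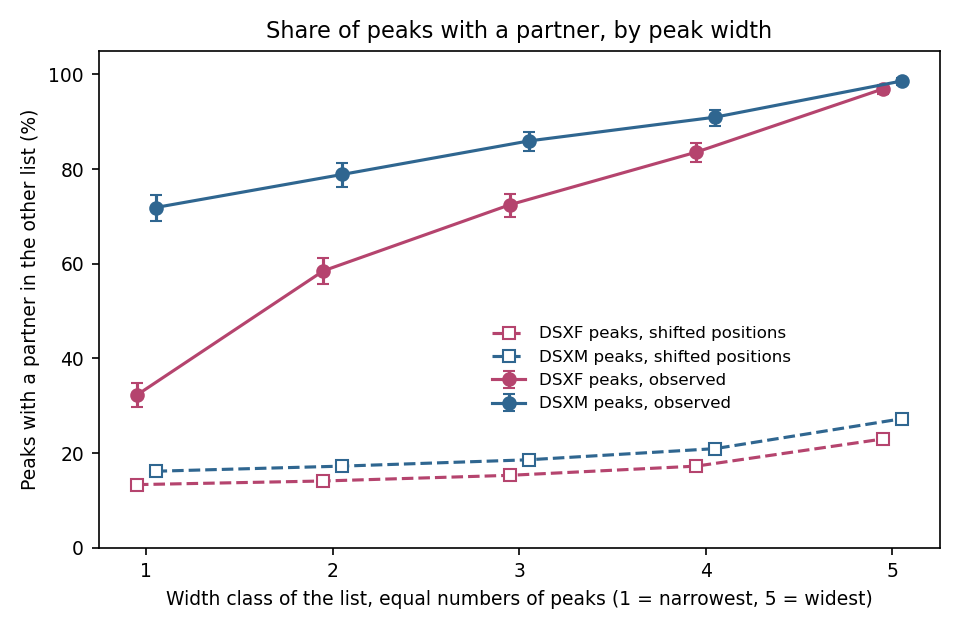
Percentage of peaks with a partner of at least 1 bp in the other list (y axis) in 5 width classes of each list from narrowest to widest (x axis), for DSXF (1304 peaks per class) and DSXM (1074 per class). Filled circles are observed shares with 95% Wilson intervals and open squares are means of 1000 circular shifts; the observed share climbs from 32.3 to 96.9% for DSXF and from 71.9 to 98.6% for DSXM.

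The broadest regions were nearly all common to both isoforms. The widest peak of either list was on chromosome X, from 12613362 to 12639005 for DSXF (25.6 kb) and from 12613793 to 12638991 for DSXM (25.2 kb). It was followed directly by a peak of 11.1 kb for DSXF (12640818 to 12651928) and 10.5 kb for DSXM (12641435 to 12651925). Another broad peak of the same cluster ran from 12552121 to 12566237 for DSXF (14.1 kb) and from 12553560 to 12566254 for DSXM (12.7 kb). Further broad pairs lay on X from 3663516 to 3675675 (12.2 kb for DSXF, 12.1 kb for DSXM), on 2R from 10367737 to 10379806 (12.1 kb for DSXF, 12.2 kb for DSXM) and on X from 7593697 to 7605409 (11.7 kb for DSXF, 10.6 kb for DSXM). Of the 10 widest DSXF peaks, 6 overlapped one of the 10 widest DSXM peaks, and each of the 10 had at least 1 partner. The second widest DSXF peak, on 3R from 3930419 to 3946428 (16.0 kb), was covered to 60.9% by 4 separate DSXM peaks. The DSXF peak on 2L from 7431455 to 7442433 (11.0 kb) was likewise met by 3 DSXM peaks, which covered 89.9% of it.

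**Figure D2:**
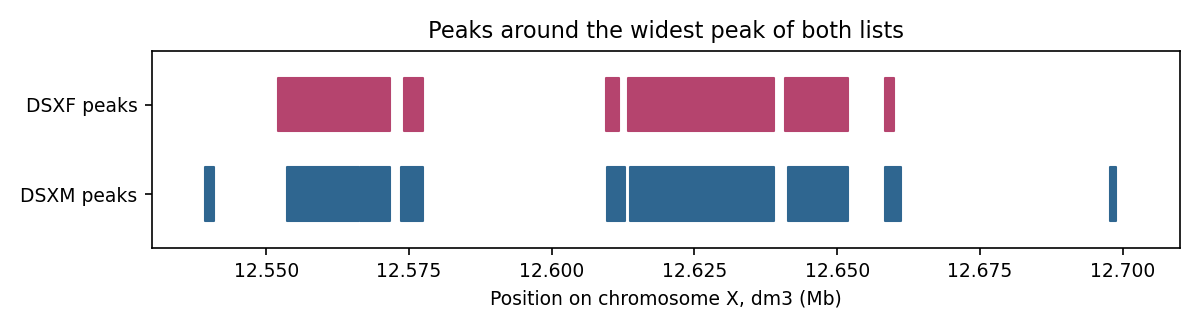
Positions of all DSXF peaks (upper row, 7 peaks) and DSXM peaks (lower row, 9 peaks) on chromosome X between 12.53 and 12.71 Mb of dm3, drawn to scale. Bars are peaks, and peaks separated by a few bp look joined; the broad peaks of 25.6, 14.1 and 11.1 kb of DSXF face DSXM peaks of 25.2, 12.7 and 10.5 kb.

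Broad regions with a single isoform were few. Of the 1304 DSXF peaks in the widest class (2579 bp or more), 40 had no DSXM partner and 34 (2.61%, 1.87 to 3.62%) had none within 500 bp. Of the 1074 DSXM peaks in the widest class (2615 bp or more), 15 had no DSXF partner and 14 (1.30%, 0.778 to 2.18%) had none within 500 bp. The widest unpartnered DSXF peaks were on 3R from 14121338 to 14125562 (4.22 kb), on X from 5570474 to 5574596 (4.12 kb), on 3R from 12887986 to 12891973 (3.99 kb), on X from 4975532 to 4979356 (3.83 kb) and on 3L from 12101383 to 12105057 (3.67 kb). The one on X at 4975532 was 138.8 kb from the nearest DSXM peak, whereas the one on 3R at 12887986 was only 0.499 kb away. The widest unpartnered DSXM peaks were on X from 17636256 to 17640472 (4.22 kb), on 3R from 21697540 to 21700874 (3.33 kb), on X from 16277228 to 16280525 (3.30 kb), on 2L from 4991340 to 4994556 (3.22 kb) and on X from 10656360 to 10659532 (3.17 kb). Among all unpartnered peaks, the median distance to the other list was 4.97 kb for DSXF and 3.73 kb for DSXM.

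The third comparison concerned the distribution over chromosomes. Peaks were spread over the arms in nearly the same proportions for both isoforms, and none of 7 exact Fisher tests of a sequence's share between the lists passed (lowest exact p = 0.237 unadjusted and 0.839 after Benjamini-Hochberg adjustment). These tests treat the lists as independent, although 68.8% of DSXF and 85.3% of DSXM peaks had a partner. Such sharing makes a difference harder to detect, so the tests add little to the proportions themselves. DSXF had 57.0 peaks per Mb on 2L, 58.6 on 2R, 57.8 on 3L and 59.1 on 3R, and DSXM had 45.4, 47.4, 48.9 and 49.5 peaks per Mb on the same arms. The X chromosome held 835 DSXF peaks (37.5 per Mb) and 675 DSXM peaks (30.3 per Mb). The density on X was 0.645 times that of the 4 autosome arms together for DSXF (95% exact interval 0.599 to 0.693) and 0.633 times for DSXM (0.583 to 0.686). Densities were taken over the stretch from the first to the last peak of each sequence in either list, 22.3 Mb for X and 96.4 Mb for the autosome arms. The small chromosome 4 held 51 DSXF peaks (40.9 per Mb) and 53 DSXM peaks (42.5 per Mb). Heterochromatic and unplaced sequences held 26 DSXF and 23 DSXM peaks, of which 17 had a partner in either list.

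**Figure D3:**
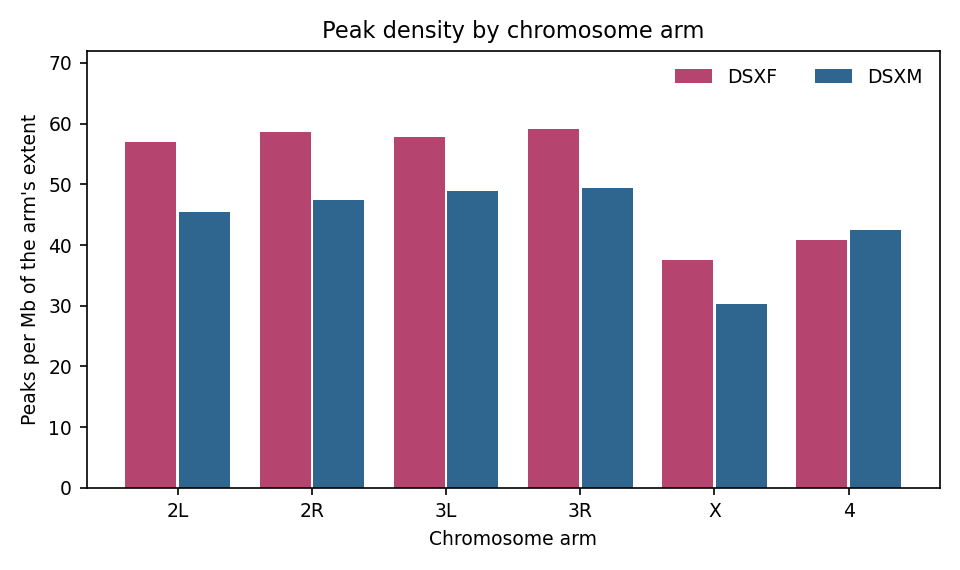
Peaks per Mb (y axis, from 0) on each chromosome arm (x axis) for the DSXF and DSXM lists, over the stretch from the first to the last peak of the arm. Bars are single pooled lists without replicates; the autosome arms stand at 57.0 to 59.1 for DSXF and 45.4 to 49.5 for DSXM, above X at 37.5 and 30.3.

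The share of peaks with a partner was lower on X, and the share that shifted positions gave was lower there too. On X, 63.6% of DSXF peaks had a partner against 69.5% on the other main sequences, a difference of -5.94 percentage points (exact Fisher test, Benjamini-Hochberg adjusted over 12 tests, p = 0.004). For DSXM the shares were 79.6% on X and 86.1% elsewhere, a difference of -6.57 points (adjusted exact p = 0.000187). The same differences in shifted positions were -5.22 points for DSXF (central 95% of 1000 shifts, -7.74 to -2.62) and -6.04 points for DSXM (-9.24 to -3.00), and the observed differences lie within these ranges. Shifts describe lists without true partners, whereas placement can add partners only to peaks that lack a true one. The ranges from shifts therefore overstate what placement adds, here and below, and do not show that it accounts for the differences. In a comparison added after these values were seen, X minus the autosome arms averaged within the 5 width classes, the DSXF difference was -10.05 points and lay below the central 95% of shifts (-8.31 to -3.14, with 4 of 1000 shifts as low), and the DSXM difference was -8.12 points and lay within it (-9.74 to -3.45). On 3L the DSXF share was higher than elsewhere, 71.7% against 68.0% (adjusted exact p = 0.0235), a difference of 3.72 points where shifts gave 1.81 (-0.634 to 4.54). On chromosome 4, 37 of 53 DSXM peaks (69.8%) had a partner against 85.5% elsewhere (adjusted exact p = 0.0125), and 38 of 51 DSXF peaks (74.5%) against 68.7% (adjusted exact p = 0.539). The DSXM difference on chromosome 4 was -15.6 points, where shifts gave -5.42 (-14.7 to 4.77). The remaining 7 tests, on 2L, 2R and 3R in either list and on 3L for DSXM, gave adjusted exact p-values from 0.188 to 0.895.

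Along the arms, both isoforms were dense and sparse in the same places. Over 121 bins of 1 Mb on the 5 main arms, the numbers of DSXF and DSXM peaks were related with Spearman's rho = 0.945, above a mean of 0.252 and a highest value of 0.627 in 1000 circular shifts. Within arms rho was 0.898 on 2L, 0.855 on 2R, 0.964 on 3L, 0.932 on 3R and 0.943 on X. Most peaks of each list had a partner in the other, and shifts undo that sharing. The excess of rho over shifts is therefore not a result separate from the overlap. The densest bin was on 2L between 8 and 9 Mb, with 106 DSXF and 88 DSXM peaks, followed by 3L between 3 and 4 Mb with 91 and 79. The sparsest complete bins were X between 0 and 1 Mb with 9 DSXF and 2 DSXM peaks, 3L between 23 and 24 Mb with 7 and 7, and 2R between 0 and 1 Mb with 12 and 3. In bins of 50 kb, 1657 of 2381 held peaks of both isoforms, 223 of DSXF alone, 70 of DSXM alone and 431 (18.1%) of neither. The highest number in such a bin was 12 for either isoform. It was reached by both on 2L from 20850001 to 20900000, by DSXF on 3L from 8650001 to 8700000 (12 DSXF and 10 DSXM peaks) and on 3R from 12100001 to 12150000 (12 and 8), and by DSXM on 2R from 9850001 to 9900000 (10 and 12). On the main arms and chromosome 4, the longest stretches free of both were on X from 21295068 to 21834336 (0.539 Mb) and on 3L from 24023630 to 24529970 (0.506 Mb).

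**Figure D4:**
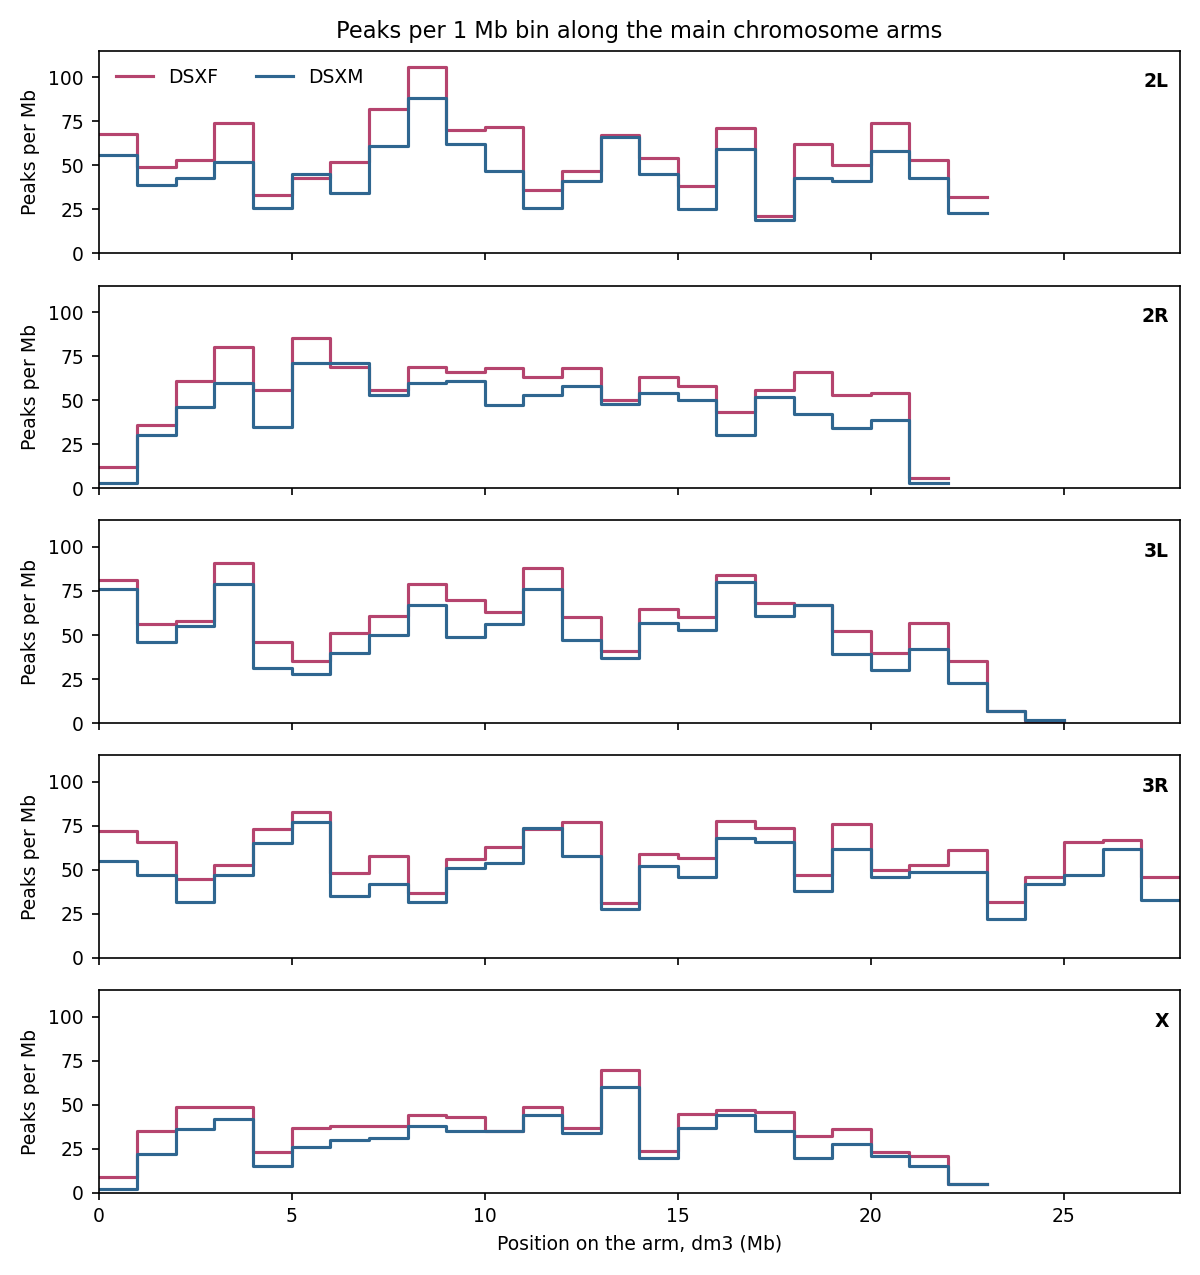
Number of peaks per 1 Mb bin (y axis) by position on dm3 (x axis, Mb) for the 5 main arms, with DSXF and DSXM as separate lines. The last bin of an arm is incomplete; the lines rise and fall together, with the maximum of 106 DSXF and 88 DSXM peaks on 2L between 8 and 9 Mb.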

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

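For the shares with a partner, the other partner definitions, the uniform placement and the restriction to placed sequences were planned, as was the restriction to shared peaks for the density on X; the alternatives based on width, and all those for the width difference and the relation of widths, were chosen after seeing the data. Both shares were above their shifts under every alternative; that the DSXM share is the higher follows from its shorter list and was not tested by them. The shares for DSXF and DSXM were 64.5% and 78.3% with a reciprocal overlap of 50% (14.02 times the shifted mean for both), and 52.0% and 63.1% with centres within 200 bp (28.7 times for both). With a gap of up to 500 bp they were 71.1% and 86.7% (3.56 and 3.61 times). In the wider 50% of each list they were 71.8% and 88.6% (6.10 and 6.24 times) and in the widest 25% 71.6% and 88.2% (9.06 and 9.25 times). With equal numbers of the widest peaks (2685 of each) they were 79.0% and 80.9% (6.48 and 6.55 times). Equal lengths make the shares nearly equal by construction. In these settings both lists were cut, so a wide peak whose partner fell below the other cut counted as unpartnered. Against the uncut DSXM list, 96.9% of the widest of 5 DSXF width classes had a partner. Without heterochromatic and unplaced sequences the shares were 68.8% and 85.3%, and uniform placement gave ratios of 4.196 and 4.245. The width difference between partnered and unpartnered peaks passed the permutation test under all settings run for DSXF (286 to 718 bp). For DSXM the difference was 24 bp with centres within 200 bp and did not pass. Under that rule 1979 DSXM peaks were unpartnered, against 792 without any overlap, so most of the 1979 overlapped a DSXF peak. The setting therefore does not test whether DSXM peaks without any overlap are narrower. The permutation test makes no allowance for wider peaks overlapping a partner more often by placement alone. The relation of widths had a rho of 0.773 over all overlapping pairs and 0.860 without the 2 peaks farthest from the median width. The rho of 0.903 with a reciprocal overlap of 50% is no test of it, since that rule admits only pairs whose widths differ by at most 2-fold. Shifted pairs were computed for the main set only. The density on X relative to the autosome arms was 0.590 for DSXF among shared peaks alone and 0.735 for DSXF and 0.717 for DSXM in the wider 50% of each list, below 1 in each case. No paired analysis was possible because each isoform has 1 list of pooled replicates. Alternatives planned on scores, annotation, motif or gene lists were not run.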

Other observations

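The splits by width on X, the shifts on X and the widest peaks on X were chosen after the pooled values were seen. The tests of why DSXF peaks lack a partner and of why X has fewer peaks had their outcomes written down first. The former were written for the larger DSXM share with a partner and in part use peak width, a choice made after seeing the files. The low density of peaks on X was deepest among narrow peaks. In the narrowest of 5 width classes of the DSXF list, X held 5.34 peaks per Mb against 12.2 on the autosome arms, a ratio of 0.438 (95% exact interval 0.36 to 0.53), and in the widest class the ratio was 0.744 (0.634 to 0.868). For DSXM the ratios were 0.466 (0.376 to 0.571) and 0.701 (0.585 to 0.835). Of the 10 widest peaks of either list, 5 were on X, the same regions in both lists, and 3 of them belong to the single cluster described above. Peaks of 5 kb or wider showed no such excess for DSXF, with 3.83% of X peaks (32) against 3.82% of autosome peaks (214); for DSXM the shares were 4.15% (28) and 3.38% (156), a difference that was not tested.

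The larger DSXM share with a partner is arithmetic, since 4483 and 4578 partnered peaks are divided by 6520 and 5370; what was weighed is why 2037 DSXF peaks had none. One technical explanation is that weaker DSXF sites were missed in the DSXM list, as with a lower depth or a stricter threshold; it predicts that unpartnered DSXF peaks gather among the narrow ones. After subtracting the shifts, the share with a partner was 55.0 percentage points higher in the widest than in the narrowest width class of DSXF peaks. This meets the prediction as far as width follows strength, which the lists cannot show. It does not favour this explanation, since DSXF-specific sites or erroneous calls among narrow peaks would give the same gradient. Shifts overstate what placement adds, so the subtraction is approximate. Displaced edges or splits are argued against as the main source, since unpartnered DSXF peaks lay within 500 bp of a DSXM peak only 3.40 percentage points more often than in shifts. DSXF-specific binding at whole peaks of the widest class is argued against as the main source too. Of that class, 2.61% had no DSXM peak within 500 bp. This value comes from the same width classes as the 55.0 points and is not a separate test. It counts a peak as shared when any part lies near a DSXM peak, so DSXF-specific binding inside broad peaks could not be detected. The share was 15.3% in the next narrower class and 25.2% in the middle class. Isoform-specific binding at narrower peaks, or inside broad ones, stays open and needs replicates or read counts.

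X had fewer peaks per Mb than the autosome arms in both lists. Merging of X peaks into fewer, wider ones is argued against as the whole explanation, since the covered length per Mb on X was 0.704 times that on the autosome arms for DSXF. Lower detection on X, for example from a lower copy number of X in these cells, stays open. The share of DSXF peaks with a partner, X minus autosome arms, was -5.90 percentage points (95% interval -9.42 to -2.48). The value meets the outcome written in advance for lower detection, over 5 points lower, but its interval spans that bound. For DSXM the difference was -6.76 points. Shifts gave -5.24 points for DSXF and -6.11 for DSXM. They describe lists without true partners, so they cannot show how much of any such difference is due to placement. Averaged within width classes the difference was -10.05 points for DSXF, below the central 95% of shifts (-8.31 to -3.14), and -8.12 points for DSXM, within it (-9.74 to -3.45). The design names no biological difference between the chromosomes, and gene density was not tested.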
